A study of Homo sapiens with 8 samples.

How the data were processed

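Total RNA from HBL-1 and BJAB cells was labelled with biotin and hybridised to 8 single-colour Affymetrix arrays, 2 for each of the 4 combinations of cell line and ligand (APRIL or EDA, 1 µg/ml, 6 h). The deposited values are log2 signals that the authors made with RMA, a background correction, quantile normalization and probe summary, in Affymetrix Expression Console, per the submitters' processing notes, which state no versions. The values ran from 2.36 to 19.38, which was taken as a log2 scale, and the RMA step itself could not be checked from them. The labels state neither the annotation release nor the genome build, so no coordinates are given.

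The deposited values cover 138745 transcript clusters, a count that includes 186 rows of controls. The annotation supplied with it pairs 36176 of them with 1 gene symbol, 1119 with several and 101450 with none. Before the data were examined it was fixed that clusters with exactly 1 symbol would be tested, with 1 cluster per gene, the one with the highest mean over all arrays, and with no filter on dim genes. This gave 33616 genes, of which 1576 had more than 1 cluster (at most 53). The reference gene table, of assembly GRCh38.p14, was used for names, gene type and chromosome alone, and 24324 genes were matched to it by gene number, 17338 of them protein-coding. Arrays give no read depth, and the number of arrays limits the precision: the median standard error was 0.25 for a comparison within a line and 0.17 for the average over both lines, and the median half-width of the 95% confidence interval was 0.55 and 0.39.

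Each gene was fitted with 1 mean per group in limma (lmFit and eBayes), with 4 residual and 6.02 prior degrees of freedom. The contrasts were APRIL minus EDA in HBL-1, in BJAB and on average over both lines, the difference of the responses, and HBL-1 minus BJAB under EDA. P-values are two-sided and were adjusted by the Benjamini-Hochberg method over the 33616 genes, with a threshold of 0.05. Every adjusted p given for a gene is limma's, and every adjusted p given for a list is that of camera, in limma, with a preset inter-gene correlation of 0.01, adjusted over the 31 lists. Camera with an estimated correlation and fry, which tests whether the members move on balance in 1 direction, were run beside it. Fry gave no list for any APRIL contrast and 13 lists for the lines.

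The 31 gene lists were written before the data were examined, from general knowledge of B-cell biology, and hold 715 entries for 661 genes, of which 649 entries and 599 genes were measured, 12 through an older symbol. Some genes stand in more than 1 list. The other list entries were not used here. List members were also adjusted over their list alone.

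The rule for naming genes was fixed beforehand too. It took the 10 largest rises and falls among genes that passed with groups that did not overlap, or the 5 smallest p-values in each direction where fewer than 5 genes passed, then 10 genes of APRIL and EDA biology, and then, for each list described, up to 4 passing members with the smallest p, or 2 members where none passed. Genes of multigene families such as immunoglobulin segments, histones and small RNAs, and those with provisional symbols, were counted but not named among the largest. After the values were seen, 2 sex-linked genes that the rule selected were also counted but not named. Members that passed over their list alone were named as well.

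Alternatives changed 1 choice at a time: leaving out dim genes, testing every transcript cluster, averaging the clusters of a gene, making array medians equal, another quantile normalization, an intensity trend with robust shrinkage, array weights, the arrays of 1 comparison alone, a replicate block, and leaving out each array in turn. Cyclic loess between arrays, protein-coding genes alone, and a comparison of list medians with 2000 random lists matched on mean level in 20 bins were added after the data were seen. The genes of a random list were drawn singly. Such lists lack the correlation between members of a fixed list, so their ranges can be too narrow.

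The procedure was tested on simulated values for the 33616 genes, with 100 genes changed at each fold and spreads drawn from the fitted model. At 4-fold it recovered 89% of the changed genes in HBL-1, 83% in BJAB, 100.0% on average over both lines and 5% for the difference of responses. At 2-fold it recovered 5% in HBL-1, 2% in BJAB, 56% on average and 0% for the difference of responses. Between 0 and 7 unchanged genes were called per comparison. Lists shifted by 0.4 passed in 3 of 3 cases in each comparison, and 0 lists that were not shifted passed in HBL-1 and 1 in each of the others. The simulated genes varied independently, and no simulated array was shifted with brightness. In the real values the estimated correlation within a list ran from 0.06 to 0.48, so the simulated list counts do not carry over to the lists below. The calculations used R 4.3.3, limma 3.58.1 and the data.table package, version 1.17.8, and figures were drawn with Python 3.11.15 and matplotlib 3.10.9.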

Results

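RNA levels were measured on 8 human Affymetrix arrays from 2 B-cell lymphoma lines, HBL-1 and BJAB, kept for 6 h with APRIL or with EDA, each at 1 µg/ml. HBL-1 is widely used as a model of the activated B-cell type of large-cell lymphoma, and BJAB is usually grouped with lymphomas of germinal-centre type. APRIL (TNFSF13) is a ligand of the tumour necrosis factor family that binds the receptors BCMA (TNFRSF17) and TACI (TNFRSF13B) and heparan sulfate chains of syndecans such as SDC1. EDA, ectodysplasin A, is a ligand of the same family with other receptors (EDAR and EDA2R), and the labels give it as the control. The design had 4 groups with 2 arrays each. None of the 8 arrays was of cells kept without a ligand, so a difference between APRIL and EDA can come from either ligand. The title of the series concerns delivery of APRIL to BCMA and the immunogenicity of lymphoma cells, so genes of antigen presentation, costimulation and immune regulation were followed beside the receptors. The labels do not say whether the 2 arrays of a group came from separate cultures, so every p-value below measures spread between arrays that may be technical.

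The arrays were close to one another within a line. Across 33616 genes the correlation was 0.989 to 0.993 between replicates, 0.988 to 0.993 between ligands within a line, and 0.942 to 0.946 between lines. The median gene level lay between 5.58 and 5.74 on the log2 scale, and the highest value was that of HBL-1 APRIL replicate 2. The same array had the highest median of the background probe sets, 3.77, where the other 7 arrays lay between 3.57 and 3.65. The median standard deviation between replicates was 0.17 for HBL-1 EDA, 0.22 for HBL-1 APRIL, 0.15 for BJAB EDA and 0.16 for BJAB APRIL. In HBL-1 the median difference of all genes between APRIL and EDA was 0.10. With the genes ordered by level into 10 groups of equal size, it was 0.04 in the dimmest group and 0.22 in the ninth, where HBL-1 APRIL replicate 2 lay 0.35 above the EDA mean and replicate 1 lay 0.10 above it. The median difference of all genes became 0.00 after another quantile normalization and 0.02 after cyclic loess, and it was 0.20 over protein-coding genes alone. In BJAB it was 0.00. For 64 genes abundant in BJAB and low in HBL-1, with RAPGEF5 among them, the median difference of HBL-1 APRIL replicate 2 from the mean of the other 3 HBL-1 arrays was 0.47, and 52 of them lay above that mean. It was 0.43 for 165 genes of the same HBL-1 level that were at least 2-fold lower in BJAB and 0.11 for genes of similar level in both lines, and the choice of these genes used that array as well.

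**Figure D1:**
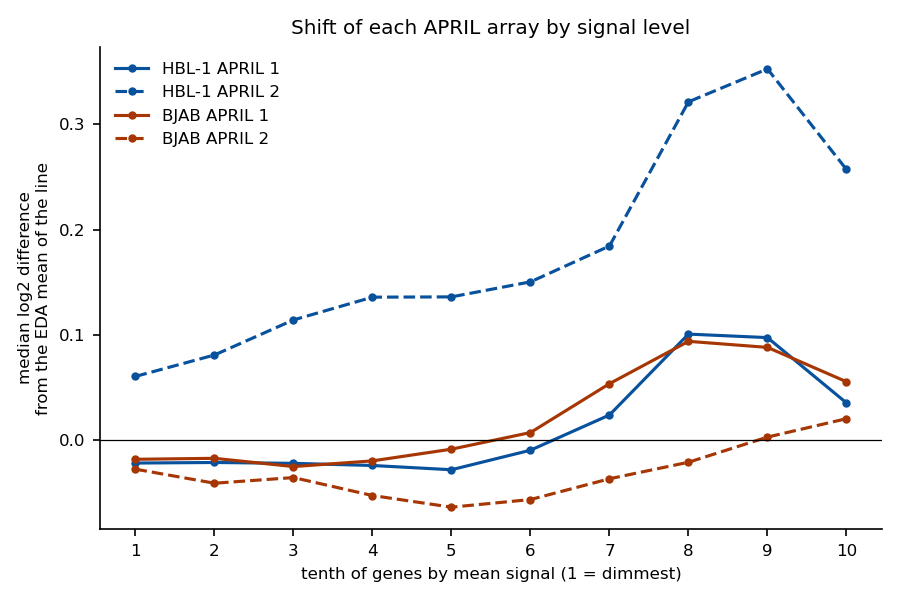
Median difference of each APRIL array from the mean of the EDA arrays of its line (log2, vertical axis) in 10 equal groups of genes ordered by mean level from dim to bright (horizontal axis), with 1 line per APRIL array. HBL-1 APRIL replicate 2 goes from 0.06 in the dimmest group to 0.35 in the ninth, while HBL-1 APRIL replicate 1 reaches 0.10.

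The comparison of the lines under EDA gives their state in the control condition and the level of the APRIL receptors. TNFRSF17, the receptor BCMA of plasma cells and late B cells, was at 11.33 in HBL-1 and 6.31 in BJAB (log2 difference 5.02, SE 0.32, n = 2 arrays per line). TNFRSF13B, the receptor TACI, was at 10.15 in HBL-1 and 5.02 in BJAB (difference 5.13, SE 0.45). The immune-regulatory cytokine IL10 was higher in HBL-1 (13.85 against 11.92, adjusted p = 0.0003), as was CD274, which encodes the checkpoint ligand PD-L1 (9.55 against 6.18). CIITA, the master regulator of MHC class II genes, was lower in HBL-1 by a log2 difference of -0.81 (adjusted p = 0.031), and EDA2R was higher by 1.21 (adjusted p = 0.019). TNFSF13 (-0.77, adjusted p = 0.052), SDC1 (-0.40) and EDAR (-0.28) did not pass. TNFRSF13C, the receptor of the related ligand BAFF, is not analysed here. Of the 19 measured ligands, receptors and adaptors of this family, 4 were higher and 2 lower in HBL-1, among them TANK (2.42) and TRAF3 (-2.43), which act in signalling below these receptors.

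**Figure D2:**
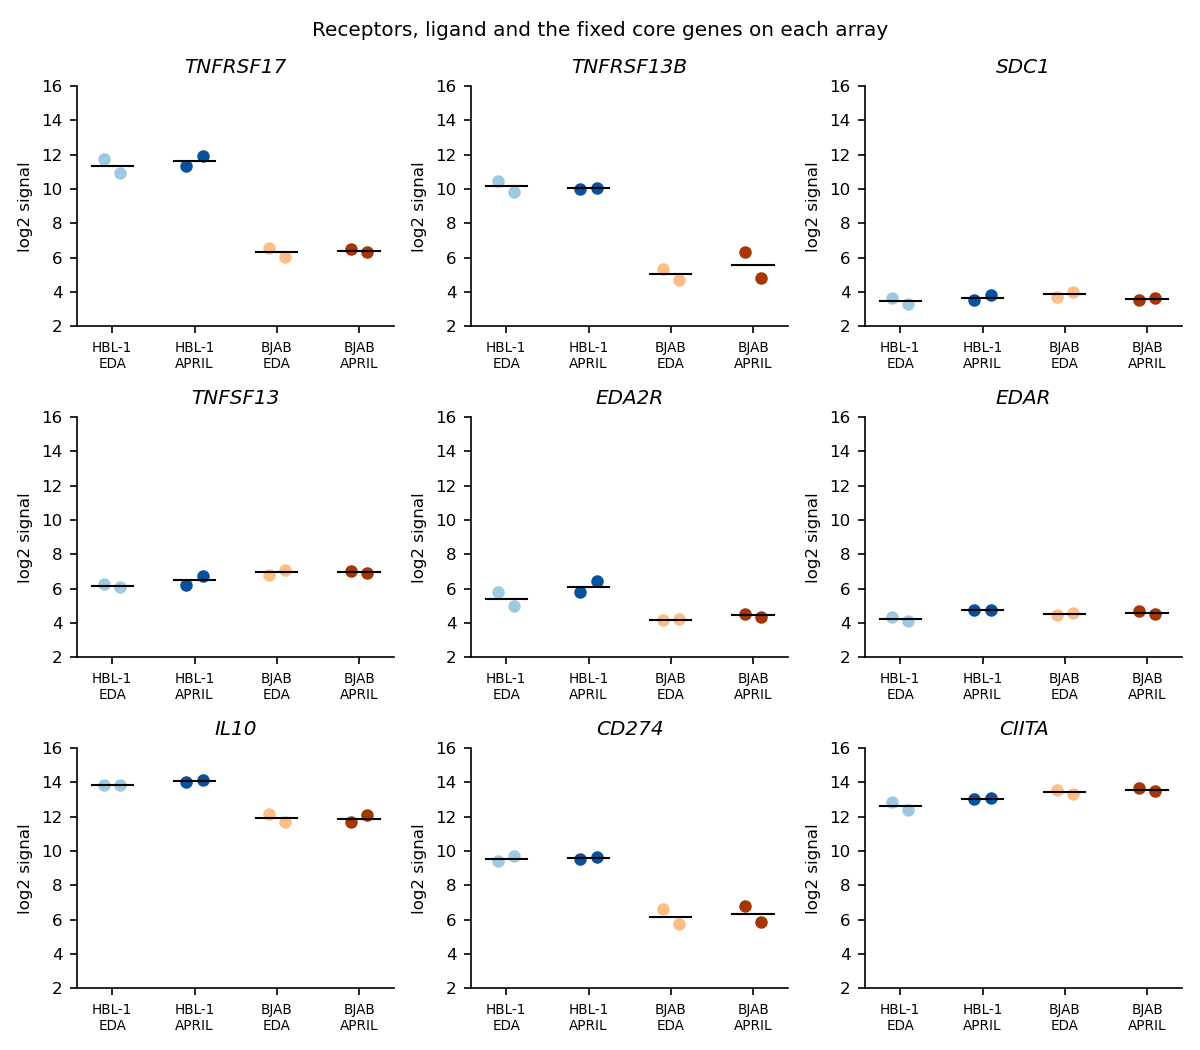
Levels (log2, vertical axis) of the APRIL and EDA receptors and ligands, IL10, CD274 and CIITA in the 4 groups, with 1 dot per array and a line at the mean of the 2 arrays of a group. TNFRSF17 sits at 11.33 in HBL-1 EDA and 6.31 in BJAB EDA, and no gene shown differs between APRIL and EDA at an adjusted p under 0.05 in either line.

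Among the genes that the naming rule allowed, TMEM123, a cell-surface mucin-like protein, had the largest difference between the lines. It was at 17.18 in HBL-1 and 4.53 in BJAB (difference 12.66), and CCND2, which encodes cyclin D2, was at 17.92 and 6.94 (difference 10.98). The other genes with the largest excess in HBL-1 were the cancer-testis genes CT45A1 (12.02), CT45A5 (11.90), CT45A10 (11.52), CT45A8 and CT45A9 (both 11.48, with identical values) and CT45A2 (11.38), the pseudogene RDXP2 (10.93) and the calcineurin regulator RCAN2 (10.30). PSMD9, a chaperone of proteasome assembly, was at 3.92 in HBL-1 and 14.82 in BJAB (-10.89), and JCHAIN, the joining chain of secreted IgM and IgA, was at 6.86 and 16.57 (-9.71). DDAH1 (-9.42), the transcription factor TOX (-9.42), the peroxidase PRDX2 (-9.35), the neuropeptide gene NMU (-8.93), the Rap exchange factor RAPGEF5 (-8.91), the ceramide synthase CERS6 (-8.86) and the potassium channel KCNN3 (-8.69) followed. PSMD9 and RAPGEF5 (3.97) lay near the background medians in HBL-1, which limits how large a difference the arrays can show. With limma, 5564 of 33616 genes differed at an adjusted p under 0.05, 2091 higher and 3473 lower in HBL-1, and 4323 of them by at least 2-fold. The split by direction depended on scaling: it was 2570 higher and 3031 lower after another quantile normalization, and 2539 and 3013 after cyclic loess. The arrays of the lines did not overlap for 18479 genes, 55.0% against 33.3% by chance.

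Marker genes of lymphoma types separated the lines. Of 18 measured markers of the activated B-cell type, 17 were higher in HBL-1 and none was lower, with a median difference of 4.92 (camera adjusted p = 1.1e-28). They included CCND2, IRF4 (9.39), a transcription factor of activated B cells and plasma cells, CYB5R2 (7.35) and ENTPD1 (8.42), the ectonucleotidase CD39. Of 16 germinal-centre-type markers, 15 were lower and 1 was higher in HBL-1 (median -2.19, camera adjusted p = 4.3e-14), with SERPINA9 (-8.24), S1PR2 (-8.16), GCSAM (-5.77) and STAP1 (-5.64) among the lower ones. Both calls miss the threshold at an adjusted p of 0.059 with an estimated correlation. Of 28 interferon-response genes, 25 were higher and 2 lower in HBL-1 (median 4.15, camera adjusted p = 1.1e-28, adjusted p = 0.108 with an estimated correlation). IFI44L (8.92), MX2 (6.68), IFIT3 (6.62) and IFI27 (6.45) had the smallest p-values in that list.

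Genes of antigen presentation and costimulation differed in both directions. Of 17 MHC class II presentation genes, 12 were lower and 2 higher in HBL-1 (median -1.67, camera adjusted p = 5.1e-07, adjusted p = 0.383 with an estimated correlation). The protease LGMN (-4.50) and the class II chains HLA-DQA1 (-4.34), HLA-DPB1 (-4.17) and HLA-DQB1 (-3.81) were among the lower ones. Of 19 MHC class I presentation genes, 4 were higher and 2 lower, with ERAP2, a peptide-trimming aminopeptidase, lower by a difference of -3.77 and the class I regulator NLRC5 higher by 1.24. Of 30 costimulatory and checkpoint genes, 4 were higher and 10 lower, including the T-cell costimulatory ligand CD86 (-8.31) and the adhesion ligand CD58 (-7.62); the list missed the threshold (camera adjusted p = 0.101). Of 23 immunoregulatory B-cell genes, 7 were higher and 3 lower (median 0.19, camera adjusted p = 0.042), with ENTPD1 and LGALS1 (3.65) higher and CD38 lower (-4.97). Of 20 genes of the IL-10 and STAT3 pathway, 7 were higher and 4 lower (median 0.18, camera adjusted p = 0.042), with the kinases PIM1 (7.62) and PIM2 (3.45) and the transcription factor BATF (4.94) higher.

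Of 28 NF-kB target genes, 11 were higher and 5 lower in HBL-1 (median 0.23, camera adjusted p = 0.042); the IkB-family genes NFKBIZ (4.35) and NFKBIE (3.42) and the activation marker CD83 (4.74) were higher and the cytokine LTB was lower (-4.05). Of 27 apoptosis regulators, 11 were higher and 4 lower (median 0.33, camera adjusted p = 0.011), with the inhibitor of apoptosis BIRC2 (7.21) and BCL2 (3.62) higher and BCL2L1 lower (-4.74). Of 25 Golgi structure and coat genes, 7 were higher and none lower (median 0.35, camera adjusted p = 0.011), including the mannosidase MAN2A1 (2.86) and the coat subunit ARCN1 (1.77). The adjusted p of these 3 lists and of the preceding pair of small shifts was 0.782 with an estimated correlation. Of 21 chemokine receptor, adhesion and migration genes, 8 were higher, including CXCR4 (8.19), CCR7 (5.82) and GPR183 (5.51), and 6 lower, including S1PR2; their median was -0.11 and their mean 1.10. The median and the mean also had opposite signs for cytokines and chemokines (-0.09 and 0.61) and for cell-cycle genes (-0.23 and 0.33). Markers of cells that a pure B-cell culture lacks were counted too. Of 17 T-cell and NK-cell markers 1 was higher and 4 lower, and none of 16 myeloid markers passed. Of 13 epithelial and fibroblast markers 3 were higher and 2 lower, with CD3G (-6.26) and DCN (-6.77) the farthest from 0. Over all genes 5564 of 33616 passed, and these counts do not show whether either culture held such cells. Counts also depend on the transcript cluster used. For ITGAM, SULF2 and COL1A1 the brightest cluster, used here, was not the one matched to the reference gene table. Its difference was -0.40, -0.15 and 0.87, and that of the matched cluster was -1.71, 1.59 and -0.15.

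Of the 31 fixed lists, 9 passed between the lines with limma's camera at its preset correlation, 7 higher and 2 lower in HBL-1, and 0 did with an estimated correlation (14 had an unadjusted p under 0.05 at the preset). The number of genes that differed fell to 3686 without BJAB EDA replicate 1, and the lists of NF-kB targets, immunoregulatory genes and the IL-10 and STAT3 pathway passed in 10, 9 and 10 of 18 alternatives, over which their medians ran from 0.07 to 0.81, from 0.17 to 1.32 and from 0.06 to 0.25.

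**Figure D3:**
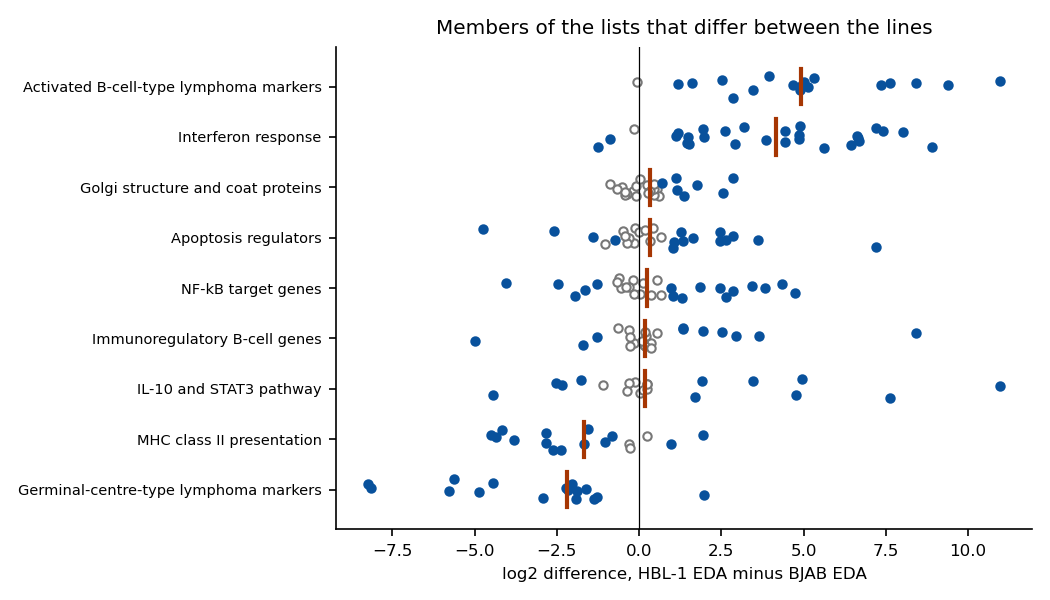
Log2 difference between HBL-1 and BJAB under EDA (horizontal axis) of the members of fixed gene lists, with 1 dot per gene (spread vertically for legibility), filled where the adjusted p was under 0.05, and a red bar at the list median. Activated B-cell-type markers have a median of 4.92 and interferon-response genes of 4.15, while germinal-centre-type markers have a median of -2.19 and MHC class II genes of -1.67.

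The first ligand comparison asked which genes differed between APRIL and EDA in HBL-1, the line with the higher level of TNFRSF17 and TNFRSF13B. SEC16B, a protein of endoplasmic reticulum exit sites, rose from 5.22 to 7.24 (log2 difference 2.02, SE 0.20, 95% confidence interval 1.58 to 2.47, n = 2 arrays per group, limma adjusted p = 0.049), and both APRIL arrays lay above both EDA arrays. It was the single gene of 33616 at an adjusted p under 0.05. The other genes with the smallest p-values did not pass after adjustment: RAPGEF5 (3.97 with EDA, difference 1.53, and 12.88 in BJAB with EDA), the palmitoyltransferase ZDHHC23 (7.98 with EDA and 9.48 with APRIL), the autophagy gene ATG16L1 (1.69) and the Ral exchange factor RGL1 (1.39) had positive differences. BCHE, which encodes butyrylcholinesterase (6.20 with EDA and 4.51 with APRIL), the pseudogenes RSU1P3 (-1.12) and PIEZO1P1 (-1.02), the metalloproteinase ADAM19 (-1.11) and the non-coding CASC20 (-1.30) had negative ones. RAPGEF5 was at 5.34 in HBL-1 APRIL replicate 1 and at 5.67 in replicate 2. ATG16L1 has 19 transcript clusters, whose differences ran from -0.13 to 1.69. The value of 1.69 is from an unmapped cluster, and the cluster on the gene's own chromosome 2 had a difference of 0.34.

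The receptors and the immune-regulatory genes named for every comparison did not pass in HBL-1. The differences were 0.30 for TNFRSF17 (95% confidence interval -0.41 to 1.02), -0.12 for TNFRSF13B, 0.30 for TNFSF13, 0.21 for SDC1, 0.49 for EDAR and 0.72 for EDA2R (0.06 to 1.38, adjusted p = 0.54). IL10 had a difference of 0.22 (-0.32 to 0.76), CD274 of 0.05 (-0.74 to 0.84) and CIITA of 0.41 (-0.08 to 0.91). The intervals printed here all include a difference of 0.55, the median half-width of all genes, and only that of CD274 includes one of -0.55.

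NF-kB target genes, many of which respond to receptors of the tumour necrosis factor family, were the list with the smallest p-value in HBL-1. Of 28 measured members, 25 had a positive difference, with a median of 0.36 (camera adjusted p = 0.0031), although 0 members passed over all genes. The call was lost at an adjusted p of 0.809 with an estimated correlation. Adjusted over the list alone, 2 members passed: RELB, a subunit of the non-canonical NF-kB pathway, at 12.19 with EDA and 13.16 with APRIL (difference 0.97, SE 0.21), and ICAM1, an adhesion ligand of leukocyte integrins, at 8.34 and 9.34 (1.01, SE 0.22). The median of the list lay above 99.95% of random lists matched on brightness, whose central range was 0.04 to 0.28, and above 99.6% of matched lists of protein-coding genes, while camera among protein-coding genes alone gave an adjusted p of 0.117. Without HBL-1 APRIL replicate 2 the median was 0.16.

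Lists of presentation and costimulation genes also passed at the preset correlation. Of 19 MHC class I presentation genes, 18 had a positive difference (median 0.27, camera adjusted p = 0.011), with ERAP2 (5.81 with EDA and 7.30 with APRIL) passing when adjusted over the list alone and NLRC5 at 0.65. All 17 MHC class II presentation genes had a positive difference (median 0.20, camera adjusted p = 0.011); HLA-DQB1 (6.02 and 7.12) passed when adjusted over the list alone, and LGMN had a difference of 0.78. Of 30 costimulatory and checkpoint genes, 25 had a positive difference (median 0.29, camera adjusted p = 0.011), and 3 passed when adjusted over the list alone: ICAM1, the herpesvirus entry mediator TNFRSF14 (8.38 and 9.23) and CD86 (5.09 and 6.03). Each of these lists had an adjusted p of 0.809 with an estimated correlation. Among random lists matched on brightness, the median of the class II list lay at the percentile 72.4 and that of the class I list at 95.4, both inside the central range, and that of the costimulatory list at 99, above it. Without HBL-1 APRIL replicate 2 the medians were 0.12 for class I, 0.13 for class II and 0.02 for costimulatory genes, of which 15 of 30 were then positive.

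A further 7 lists passed at the preset correlation in the same direction. They were chemokine receptors and adhesion (20 of 21 members positive, median 0.29, camera adjusted p = 0.011, with CCR10 at 0.83), apoptosis regulators (24 of 27, median 0.27, adjusted p = 0.011, with CASP10 at 0.92 and FAS at 0.83) and p53 target genes (19 of 20, median 0.34, adjusted p = 0.011, with TNFRSF10B at 0.72). Plasma cell differentiation (15 of 16, median 0.26, adjusted p = 0.018) held JCHAIN, at 6.86 with EDA and 7.79 with APRIL, which passed when adjusted over the list alone. Amino acid and integrated stress response (17 of 19, median 0.24, adjusted p = 0.028, with CHAC1 at 1.30), MYC targets and ribosome biogenesis (19 of 20, median 0.21, adjusted p = 0.031) and germinal-centre-type markers (16 of 16, median 0.32, adjusted p = 0.041) completed them. With an estimated correlation these 7 had an adjusted p of 0.809 to 0.819. Under EDA, 15 of the 16 germinal-centre-type markers and 11 of the 17 class II genes, HLA-DQB1 among them, were at least 2-fold higher in BJAB. So were CD86, ERAP2 and JCHAIN. Of 66 genes abundant in BJAB and low in HBL-1, 49 were higher in HBL-1 APRIL replicate 2 than in replicate 1 (median difference 0.40). JCHAIN was at 7.76 in HBL-1 APRIL replicate 1 and at 7.82 in replicate 2, so its rise was not confined to replicate 2. Without HBL-1 APRIL replicate 2 the medians of the 7 lists, in the order given, were 0.20, 0.13, 0.15, 0.08, 0.12, 0.11 and 0.17. Those of apoptosis regulators (percentile 92.4), plasma cell (85.9), amino acid (93.2) and MYC target genes (94.6) over all arrays lay inside the range of brightness-matched lists, and the other 3 lay above it.

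The other 20 lists did not pass in HBL-1, at camera adjusted p-values from 0.078 to 0.788. They covered the ligands and receptors themselves, immunoregulatory B-cell genes, cytokines and chemokines, the IL-10 and STAT3 pathway, immediate early genes, the cell cycle, B-cell identity, the unfolded protein response, heat shock, the interferon response, cholesterol synthesis, glycolysis and hypoxia, heparan sulfate biosynthesis, the Golgi, activated B-cell-type markers, T-cell and NK-cell, myeloid, and epithelial and fibroblast markers, cytosolic ribosomal proteins and mitochondrially encoded genes. TM7SF2, a sterol reductase (7.90 with EDA and 8.80 with APRIL), was their single member to pass when adjusted over the list alone. The median was above 0 in 31 of 31 lists, beside the median of 0.10 for all genes, and it lay above the brightness-matched range in 6 of them.

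In HBL-1 limma gave an unadjusted p under 0.05 for 2967 genes, 8.83% of those tested, 2238 of them higher and 729 lower with APRIL, and the arrays of the groups did not overlap for 12258 genes, 36.5% against 33.3% by chance. The SEC16B call was lost without any 1 of the 8 arrays (adjusted p = 0.172 to 0.314), with array weights (0.115), with the replicate block (0.155) and with the HBL-1 arrays alone (0.465), while its difference stayed between 1.91 and 2.14. The 11 lists became 0 without HBL-1 APRIL replicate 2 (adjusted p = 0.295 for NF-kB targets), 18 without HBL-1 APRIL replicate 1, 1 without HBL-1 EDA replicate 2, 4 after cyclic loess (NF-kB targets at adjusted p = 0.015) and 0 among protein-coding genes alone.

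**Figure D4:**
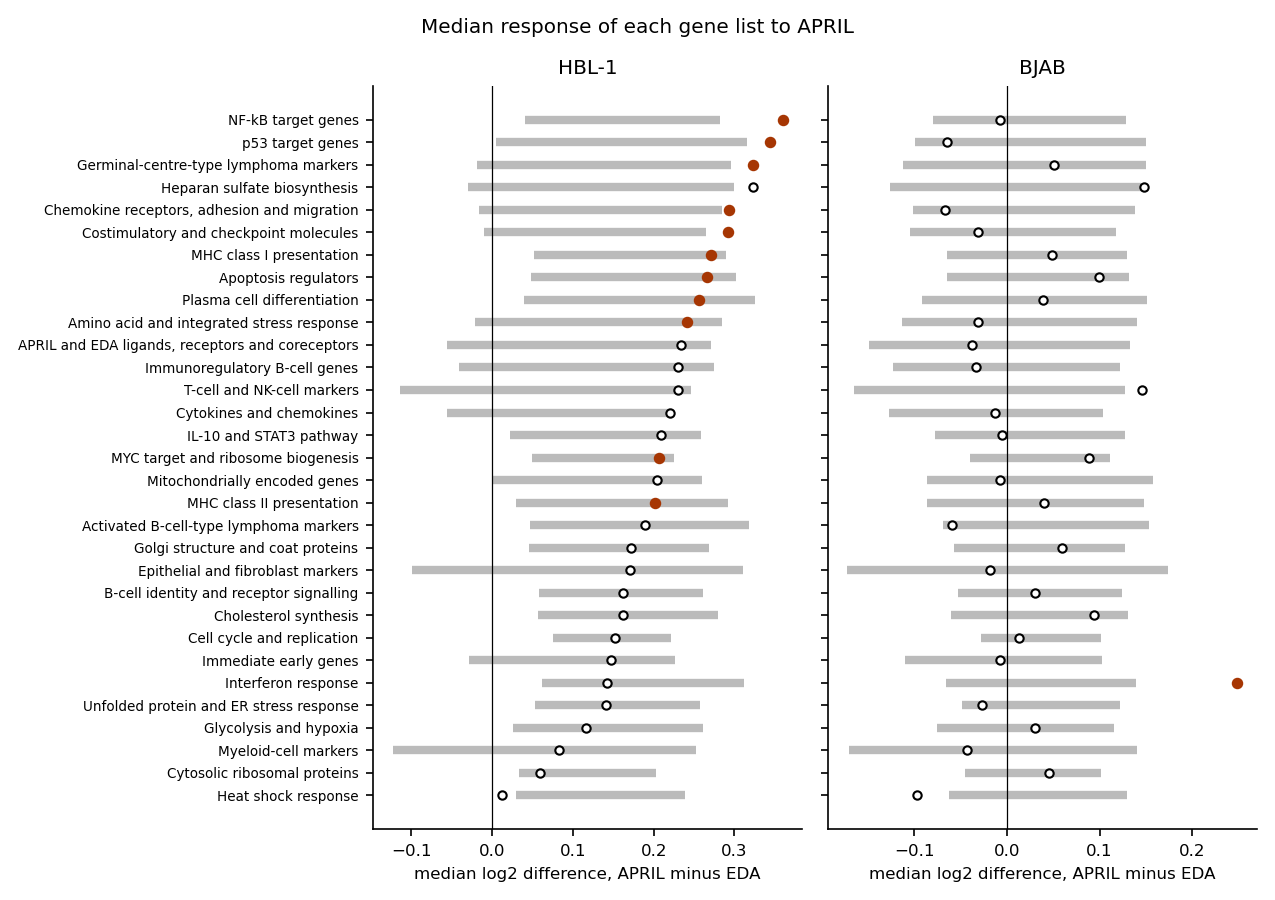
Median log2 difference between APRIL and EDA of each fixed gene list (horizontal axis) in HBL-1 and in BJAB, with 1 dot per list, filled red where the camera adjusted p was under 0.05 at the preset correlation, and grey bars for the central 95% of 2000 random lists matched on brightness. In HBL-1 the median of NF-kB target genes is 0.36 against a matched range of 0.04 to 0.28, and in BJAB that of interferon-response genes is 0.25 against -0.07 to 0.14.

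The same comparison in BJAB, the line with lower TNFRSF17 and TNFRSF13B, gave a shift of 1 gene group. Of 28 interferon-response genes, 22 had a positive difference between APRIL and EDA (median 0.25, camera adjusted p = 0.012, adjusted p = 0.998 with an estimated correlation), and the median lay above every brightness-matched random list. Those lists were drawn gene by gene, without the estimated correlation of 0.26 within this list. Medians also lay above the matched range for heparan sulfate biosynthesis (0.148 against 0.145) and T-cell and NK-cell markers (0.146 against 0.127). That of heat shock genes lay below it (-0.097 against -0.062). Adjusted over the list alone, 1 member passed, IFI44L, at 6.03 with EDA and 7.50 with APRIL (difference 1.47, SE 0.30, n = 2 arrays per group), while 0 passed over all genes. The antiviral genes RSAD2 (0.89), MX1 (0.72) and ISG15 (0.49), chosen as examples after their values were seen, were on the same side. IFIT5 was on the other (5.08 with EDA and 4.07 with APRIL). A dimmer transcript cluster of RSAD2 had a difference of -0.04. NF-kB target genes had a median of -0.01 and a mean of 0.09, with 13 of 28 members positive (camera adjusted p = 0.641).

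The genes named for every comparison did not pass in BJAB either. IL10 had a difference of -0.03 (95% confidence interval -0.58 to 0.51), CD274 of 0.15 (-0.64 to 0.94) and CIITA of 0.13. The receptors TNFRSF17 (0.10), TNFRSF13B (0.54), EDA2R (0.27) and EDAR (0.07), the ligand TNFSF13 (0.01) and SDC1 (-0.28) were within their intervals of 0. The named genes with the smallest p-values, none of which passed, were CREBRF, a regulator of the CREB3 transcription factor (6.94 with EDA and 8.29 with APRIL), the mitochondrial ATPase AFG1L (1.20), the deubiquitinase OTUD7B (1.35) and the non-coding HCG23 (1.09) and SLC9A9-AS1 (1.19) on the positive side. On the negative side they were the glucosidase MGAM (-1.41), the clathrin adaptor subunit AP1S1 (-1.88), the calcium channel CACNA1A (-1.27), the transporter gene SLC7A4 (-1.03) and the acyl-CoA synthetase ACSBG2 (-1.07). AP1S1 has a further transcript cluster of similar level, with a difference of 0.59, and MGAM a dimmer one with 0.12. For AP1S1 that further cluster is the one matched to the reference gene table.

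With limma, 0 of 33616 genes differed between APRIL and EDA in BJAB at an adjusted p under 0.05, and 1365 had an unadjusted p under 0.05 (4.06%, 689 higher and 676 lower). The arrays of the groups did not overlap for 11517 genes, 34.3% against 33.3% by chance. The interferon list missed the threshold after cyclic loess (adjusted p = 0.055), without BJAB EDA replicate 2 (0.366, median 0.17) and without BJAB APRIL replicate 1 (0.934, median 0.16).

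Averaged over both lines, 4 APRIL arrays were compared with 4 EDA arrays with the line accounted for. NF-kB target genes had a median difference of 0.16 (25 of 28 positive, camera adjusted p = 0.0035), MHC class I presentation genes of 0.22 (18 of 19, adjusted p = 0.0078) and heparan sulfate biosynthesis genes of 0.26 (16 of 20, adjusted p = 0.028). In the last list PAPSS1, which makes the sulfate donor, had a difference of 0.56 (SE 0.15) and the xylosyltransferase XYLT2 of 0.52. Apoptosis regulators (median 0.21), MYC targets (0.14), MHC class II (0.17), costimulatory (0.18), p53 target (0.16), plasma cell (0.16) and interferon-response genes (0.16) also passed, which made 10 of 31 lists, all higher with APRIL. Each had an adjusted p of 0.829 with an estimated correlation. Among random lists matched on brightness, the NF-kB median lay inside the central range of 0.01 to 0.18, at the percentile 95.25. The class I, costimulatory, apoptosis and heparan sulfate medians lay above their ranges, and those of the other lists that passed lay inside. In the class II list, 1 member, HLA-DQB1 (0.76, SE 0.18), passed when adjusted over the list alone.

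SEC16B (1.12), AFG1L (1.12), ZDHHC23 (0.99), TCP11L1 (1.27) and CPLANE1, a ciliary protein (1.03), had the smallest p-values among genes with positive average differences, and none passed. The muscle protein gene NEB (-0.85), BCHE (-0.98), the pseudogene SNX18P14 (-0.88) and AP1S1 (-1.12) were among those with negative ones; the further cluster of AP1S1 had positive differences in HBL-1 (0.23) and BJAB (0.59). The average differences of the genes named throughout were 0.20 for TNFRSF17, 0.21 for TNFRSF13B, 0.50 for EDA2R, 0.28 for EDAR, 0.16 for TNFSF13, -0.04 for SDC1, 0.09 for IL10, 0.10 for CD274 and 0.27 for CIITA. With limma, 0 genes had an adjusted p under 0.05 (smallest 0.062), 2 had one under 0.1 and 2323 had an unadjusted p under 0.05. The arrays did not overlap in the same direction in both lines for 2433 genes, 7.24% against 5.56% by chance. The 10 lists became 0 without HBL-1 APRIL replicate 2, 3 without HBL-1 EDA replicate 2, 3 without BJAB EDA replicate 2, 1 without BJAB APRIL replicate 1 and 1 (NF-kB targets, adjusted p = 0.023) after cyclic loess.

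The interaction asked whether the response to APRIL differed between the lines. The differences of response with the smallest p-values, none passing, were MGAM (1.98), SEC16B (1.81), FAM170A (1.79), the diacylglycerol kinase DGKG (1.78) and the ciliary gene WDR19 (1.73), with a larger value in HBL-1, and RSU1P3 (-1.71), PIEZO1P1 (-1.59), CREBRF (-1.37), BCRP5 (-1.32) and DLGAP1-AS5 (-1.20), with a larger one in BJAB. A dimmer transcript cluster of MGAM went the other way, with a response of -0.23 in HBL-1 and 0.12 in BJAB. The interaction estimates of TNFRSF17 (0.20), IL10 (0.25), CD274 (-0.10) and CIITA (0.28) did not pass. NF-kB target genes had a median interaction of 0.25 (camera adjusted p = 0.134) and interferon-response genes of -0.14 (adjusted p = 0.134), and neither list passed. The interferon median lay below the range of brightness-matched lists (0.01 to 0.31), and that list passed among protein-coding genes alone (adjusted p = 0.0023) and without BJAB APRIL replicate 2 (0.020), while its median was 0.13 without BJAB APRIL replicate 1 (0.715). With limma, 0 genes passed (smallest adjusted p 0.843) and 1894 had an unadjusted p under 0.05; 0 of 31 lists passed and 9 had an unadjusted p under 0.05. Across the 33616 genes, which are not independent replicates, the responses of the lines had a Pearson correlation of 0.0658 and a Spearman correlation of 0.0663. The number of lists was 7 without HBL-1 APRIL replicate 1, 1 without HBL-1 EDA replicate 1 and 1 without BJAB APRIL replicate 2.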

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

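The count in this part was planned as an alternative set of features, and no test in it was chosen after the result was seen. Transcript clusters that the annotation pairs with no gene, or with several, were not used in the comparisons above, and some of them separated the lines. With limma over all 138745 clusters, 3159 of the 102569 clusters without a single gene name differed between HBL-1 and BJAB under EDA, 1560 of them higher and 1599 lower in HBL-1. Over all 138745 clusters 7293 differed, so the unnamed ones passed less often than the named ones. For APRIL against EDA, limma called 0 of them in either line or on average. What these clusters measure was not tested.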

How the results depend on the processing

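All alternatives were fixed before the data were examined except cyclic loess, protein-coding genes alone and brightness-matched lists, which were chosen after the data were seen. The count of genes that differed between the lines stayed within 1.5 times of 5564 under every alternative except 1, 3686 without BJAB EDA replicate 1, and ranged from 3686 to 5871 over the arrays left out. Of the results for named genes between the lines, 2295 kept their direction and side of the threshold, 46 lost the call and 7 gained one. None reversed after a call.

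The single gene called in HBL-1, SEC16B, was itself removed, not tested, with dim genes left out (0 genes), since its mean level of 5.37 was below the limit. It was lost (0 genes) with every transcript cluster tested, with array weights, with the arrays of HBL-1 alone and with the replicate block, and leaving out arrays gave 0 to 0. The 11 lists of HBL-1 became 1 with dim genes left out, 3 after quantile normalization again, 4 after cyclic loess, 0 for protein-coding genes only, 0 with an estimated correlation, 0 with fry and 7 (6 higher and 1 lower) by brightness-matched lists, and 0 to 18 over the arrays left out. The list of BJAB became 0 after cyclic loess, 0 with an estimated correlation, 0 with fry and 4 (3 higher and 1 lower) by brightness-matched lists, and 0 to 1 over the arrays left out. On average over both lines, the 0 genes became 2 with dim genes left out, 1 with an intensity trend and robust shrinkage and 2 at an adjusted p under 0.1. The 10 lists became 1 with dim genes left out, 1 after quantile normalization again, 1 after cyclic loess, 1 for protein-coding genes only, 0 with an estimated correlation, 0 with fry and 5 (4 higher and 1 lower) by brightness-matched lists, and 0 to 13 over the arrays left out. For the difference of responses, the 0 lists became 1 for protein-coding genes only, 4 by brightness-matched lists, and 0 to 7 over the arrays left out. The 9 lists between the lines became 0 with an estimated correlation. The correlation of the responses, 0.0658, was 0.0823 with dim genes left out, 0.0472 over every transcript cluster and 0.0497 after cyclic loess, and 0.0370 to 0.0721 over the arrays left out. Spearman's rho was 0.0663. A correlation over called genes could not be computed, since 1 gene was called in at least 1 line. The cause was not tested for any of these changes but the first.

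Where an array was left out, the lone array of its group was assumed to vary like the others. Lists were not tested over all transcript clusters, and the arrays of 1 comparison alone gave no value for the average or the difference of responses. The replicate block left 11 lists in HBL-1 and 8 of the 10 on average. Deviations of equally numbered replicates correlated between groups at -0.02 to 0.06, so the gene values gave no clear sign of pairing. In BJAB the hybridisation controls bioB, bioC, bioD and cre were each higher in replicate 1 with both ligands. For bioB the BJAB values were 9.94 and 10.00 against 9.77 and 9.77, and in HBL-1 9.69 and 10.01 against 10.04 and 9.99. Whether arrays were processed by replicate was not tested. Background probe sets had medians of 3.57 to 3.77, and a fall of a gene near that level, such as SDC1 at 3.46 in HBL-1 EDA, was not detectable.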

Other observations

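The tests of explanations in this part and the comparisons of chromosomes and CT45A genes were chosen after the results were seen, while the gene and list comparisons between the lines and the regroupings of the arrays were planned. Beyond the lists described above, single genes of cell metabolism and stress differed between HBL-1 and BJAB under EDA in both directions. Of 19 cholesterol synthesis genes, 7 were higher and 3 lower in HBL-1, with the synthase LSS (2.90) higher and the epoxidase SQLE (-2.77) and TM7SF2 (-2.44) lower (camera adjusted p = 0.0664). Of 22 genes of the unfolded protein response, 5 were higher, including HERPUD1 (1.90) and DNAJC3 (2.06), and 2 were lower, including the chaperone HSPA5 (-1.18) (adjusted p = 0.0664). Of 19 genes of the amino acid and integrated stress response, 1 was higher, ALDH1L2 (2.25), and 6 were lower, including the asparagine synthetase ASNS (-1.35) and DDIT4 (-1.77) (adjusted p = 0.196). Heat shock genes had 1 higher and 4 lower of 13, with CHORDC1 at -1.49 (adjusted p = 0.0664), and MYC targets 1 higher and 4 lower of 20, with MYC itself at -1.77 (adjusted p = 0.0704). Of 25 glycolysis and hypoxia genes, 2 were higher and 5 lower, with the mitophagy receptor BNIP3 at 2.06 and the glucose transporter SLC2A1 at -1.92. Cytosolic ribosomal proteins (0 higher and 2 lower of 17) and mitochondrially encoded genes (0 higher and 1 lower of 7) differed little.

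Genes of differentiation and growth control also split. Of 16 plasma cell genes, 7 were higher in HBL-1, including IRF4 (9.39) and the transcription factor CREB3L2 (5.01), and 4 were lower, including JCHAIN (-9.71) and CD38 (-4.97) (camera adjusted p = 0.112). Of 23 genes of B-cell identity and receptor signalling, 6 were higher, including the adaptor BLNK (3.94), and 4 lower, including the phosphatase PTPN6 (-4.19) and MS4A1, the antigen CD20 (-2.75). Of 32 cell-cycle genes, 6 were higher, including CCND2 (10.98) and the inhibitor CDKN1A (4.85), and 9 lower, including the replication factor CDC6 (-1.60). Of 20 p53 target genes, 8 were higher and 4 lower, among them FAS (-2.59), TP53INP1 (-4.73) and GADD45A (-3.23). Of 20 heparan sulfate biosynthesis genes, 2 were higher, XYLT1 (3.23) and HS2ST1 (1.22), and 3 lower, including the epimerase GLCE (-3.07). Of 28 cytokine and chemokine genes, 7 were higher, including CXCL16 (6.16), IL7 (4.96) and IL15 (4.31), and 1 was lower, LTB (-4.05). Of 31 immediate early genes, 5 were higher, including ZFP36L1 (2.59), and 5 lower, including the phosphatase DUSP6 (-2.92). All 7 CT45A genes tested were higher in HBL-1, by 1.51 to 12.02, but CT45A8 and CT45A9 had identical values and are not separate measurements. These genes are near-identical copies on the X chromosome, and whether the arrays separate the others was not tested.

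The rise of 11 gene lists with APRIL in HBL-1 was set against a shift of the arrays with brightness, the single array HBL-1 APRIL replicate 2, a trace of BJAB RNA in that array, and a shift common to protein-coding genes. For NF-kB target genes, the tables argue against brightness as the whole cause, since the list passed after cyclic loess (adjusted p = 0.0154) although its median went from 0.36 to 0.18, and against the trace, since it passed with the largest trace that genes abundant in BJAB allow, 0.482%, taken off (adjusted p = 0.0030); over 18 refits at the preset correlation the adjusted p was 0.0010 to 0.295, and it was 0.809 with an estimated correlation. A dependence on replicate 2 and a shift common to protein-coding genes cannot be told apart from a response, and activation of NF-kB by APRIL remains an untested hypothesis, since the list median lay at the percentile 94.58 of matched lists in replicate 1 (unadjusted p = 0.019 without replicate 2), and above 99.55% of matched protein-coding lists while camera among protein-coding genes alone gave an adjusted p of 0.117. For the other 10 lists, 3 passed after cyclic loess and 1, chemokine receptors and adhesion, lay above the matched range in replicate 1, so neither brightness nor the single array can be excluded, and 0 lay above the range of protein-coding lists matched on brightness, which is consistent with a shift common to protein-coding genes. With the same trace taken off, 8 of the 10 still passed, while the plasma cell list (adjusted p = 0.0959) and germinal-centre-type markers (0.405) did not. Their medians went from 0.26 to 0.23 and from 0.32 to 0.24. A trace of BJAB RNA therefore stays open for these 2 lists, as a part of the difference.

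Of 64 genes abundant in BJAB and low in HBL-1, 52 lay higher in HBL-1 APRIL replicate 2 than the mean of the other 3 HBL-1 arrays, with a median difference over all 64 of 0.47 (95% bootstrap interval 0.35 to 0.65). That choice of genes used the array itself, so 66 genes were chosen on the EDA arrays alone, and HBL-1 APRIL replicate 2 lay above replicate 1 by a median of 0.40 (0.22 to 0.72) for them. The tables argue against a shift with brightness alone, since that median lay at the percentile 99.99 of lists of genes at similar levels in both lines, matched on HBL-1 level, and 206 genes at least 2-fold lower in BJAB had a median of 0.17 (0.03 to 0.30), where the choice on all arrays had given 0.43 for 165 genes. A trace of BJAB RNA cannot be told apart from other causes, since genes with the larger excess in BJAB should then differ more than the others, by 0.38, and the value found, -0.00869, had an interval of -0.44 to 0.62 that holds both 0 and the prediction. No biological explanation was tested.

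The higher interferon-response genes with APRIL in BJAB were set against a trace of HBL-1 RNA, where these genes are abundant, and against the single array BJAB APRIL replicate 1. For the trace, 71 other genes abundant in HBL-1 and low in BJAB had a median difference of -0.0118 (-0.20 to 0.10), below the 0.25 of the interferon list. These values show no sign of a trace. They do not exclude it, since the choice of the 71 genes used the BJAB APRIL arrays too and could leave out genes that a trace raises. Whether replicate 1 alone carries the result cannot be told apart from a response, since the list median in replicate 2 lay at the percentile 99.36 of matched lists while camera without replicate 1 gave an unadjusted p of 0.232 in a fit over the arrays left. An interferon-like response of BJAB to APRIL, or to a component of its preparation, is an untested hypothesis.

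The 8 arrays were regrouped into 4 and 4 in 35 ways, of which 34 could be fitted with the cell line accounted for. For the average over both lines, the real count was 0 genes (highest of the others 0), which all 34 of 34 splits reach by construction, so it says nothing about chance. At least the real 10 lists were given by 2 of 34 splits, the real one included (highest of the others 11), so chance cannot be excluded for the lists. The other of these splits set HBL-1 APRIL replicate 2 apart from the 3 other HBL-1 arrays. At an unadjusted p under 0.05 the real split gave 2323 genes, and 5 others gave more, up to 3735.

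A hypothesis formed from the data is that HBL-1 carries more copies of chromosomes 3 and 18 than BJAB, since gains of these chromosomes are common in lymphomas of the activated B-cell type. Over 7547 protein-coding genes with a group mean of at least 8, the median difference between HBL-1 and BJAB under EDA was -0.24, while it was 0.21 for 457 genes of chromosome 3 and 0.40 for 114 genes of chromosome 18. Both medians lay at the percentile 100 of 10000 shuffles of the gene order (adjusted p = 0.00092 over 23 chromosomes), but the 2 chromosomes were chosen for their high medians, so this does not test the hypothesis. Of the 23 chromosomes, 11 had an adjusted p under 0.05: 4 lay above the shuffled range, with 8 (0.03) and 13 (0.03) beside these 2, and 7 lay below it, namely 9 (-0.63), 5 (-0.55), 7 (-0.50), 20 (-0.49), 14 (-0.47), 15 (-0.41) and 4 (-0.40). Copy number was not measured, and the hypothesis stays open.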
